A study of Mus musculus with 24 samples.

How the data were processed

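Liver and the scraped epithelium of the duodenum, jejunum and ileum were compared between mice lacking caspase-1 (Casp1-null) and wild-type C57BL/6 mice. There were 8 groups, made by 4 tissues and both genotypes, with 3 arrays in each, 24 single-colour whole-transcript Affymetrix arrays in all. All mice were males of 14 to 16 weeks kept on chow. Livers came from mice fasted for 16 h. Intestines came from overnight-fasted mice, 2 h after a gavage of 200 µL olive oil. Each array was hybridised with material from 100 ng of total RNA with an integrity number above 8.0.

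The deposited values were log2 expression values per probe set, made by the authors with robust multi-array averaging (RMA), whose version is not given in the sources used here. They were used as deposited, without further scaling, and all 24 arrays were used. The files held 35556 probe sets, of which 21218 carried exactly 1 gene symbol, 1881 carried several and 12457 carried none. The probe sets with 1 symbol covered 18820 genes. Of these genes, 1386 had more than 1 probe set and were represented by the probe set with the highest mean over all arrays. Gene identifiers of 21185 probe sets were found in the mouse GRCm38.p6 gene table and 33 were not. That table served for names and for the order of genes along chromosomes only, because no genome build is named for the array values, and no positions are given for that reason. Array medians lay between 4.874 and 5.005 in intestine and between 5.187 and 5.224 in liver. No pair of arrays was identical.

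Differences were tested with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, with no trend). Helper packages were statmod 1.5.0, data.table (1.17.8) and jsonlite 2.0.0, and plots were drawn in Python 3.11.15 with matplotlib 3.10.9. Liver was fitted on its own 6 arrays with 4 residual degrees of freedom. The 3 intestinal segments were fitted together on 18 arrays with 12 residual degrees of freedom, so that a segment's test used a spread pooled over all segments. Wild-type jejunum was also compared with wild-type duodenum and ileum in that fit. For the mean over segments, values of the 3 segments with the same genotype and replicate number were averaged before the fit, which treats a number as a mouse although the labels do not say so. Interaction terms tested whether the genotype difference differed between segments, or between liver and the mean of the segments (all 24 arrays, 8 groups). Tests were two-sided, and p-values were adjusted by the Benjamini-Hochberg method over all 35556 probe sets. A gene was called at an adjusted p under 0.05. Changes are Casp1-null minus wild type on the log2 scale, and errors are standard deviations (SD) of 3 arrays or standard errors (SE) of the fit. The p-values measure the spread between the samples of these mice. No detection calls or background probes were used here, so a group mean under the lowest array median of its tissue was read as not shown above background, a reading chosen after the data had been seen. A change between such a group and a higher one is given as a lower bound, and no size is given where both groups were that low. The number of arrays limits the precision, and an exact permutation test of 3 against 3 arrays cannot give a p below 0.1.

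Gene groups were tested with camera from limma on 34 lists of genes, each with at least 5 measured members, at a preset correlation of 0.01. The lists covered lipid handling, other metabolism, immunity, stress, cell types, position along the intestine and neighbours of Casp1. Camera was repeated with an estimated correlation for each list, and fry from limma tested each list on its own. For the members of a list, p-values were also adjusted over the list alone. Clustering of the genes shared between tissues along the chromosomes was tested against 10000 random sets, counting members with another member within 10 named genes. Neighbours of Casp1 were tested with a two-sided Fisher's exact test.

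The lists, comparisons, tests, alternatives and the rule for named genes were fixed before the data were examined. The rule took Casp1 and, per tissue, the 10 called genes with the largest rise and the 10 with the largest fall. All 3 Casp1-null arrays had to lie outside the range of the 3 wild-type arrays. It added up to 4 members of each list by p in that tissue, the 10 genes with the smallest p for interactions and for the mean over segments, up to 20 genes called in at least 3 tissues, and for wild-type segments the members of both position lists and the 5 genes with the largest difference each way. A further list of genes induced in epithelium by bacteria was written after the jejunal result had been seen.

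Alternatives were a mean-variance trend with robust fitting, a filter at the median, quantile normalization again, median centring, array weights, the replicate number as a block, a spread from other arrays, a minimum change of 1.5-fold, random blocks for genotype and replicate number, and leaving out each array in turn. On simulated data with the arrays' own spread, changes of log2 1 were recovered for 73.1% of the changed genes in liver, 76.1% in duodenum, 83.6% in jejunum and 88.1% in ileum. False calls made up 2.44% of calls in liver, 10.1% in duodenum, 8.86% in jejunum and 41% in ileum. Where 1 spread was simulated for all segments instead, they made up 0% in duodenum and jejunum and 2.05% in ileum. The shares for the segments thus depend on how the spread was simulated. In the ileum the arrays varied more than in the other segments, so the pooled spread understated the ileal spread. With the spread of the 6 ileal arrays alone, 1.19% of calls were false and 37.3% of changes of log2 1 were recovered. False calls reached 2.45% for the mean over segments, 15.4% for the segment interaction, 20.4% for liver against intestine, 6.62% for wild-type duodenum and 16.7% for wild-type ileum. In each tissue both of the 2 lists shifted in the simulation were recovered by camera, with at most 1 false list. Simulated genes varied independently of each other, so this does not show how often correlated genes give false lists.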

Results

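Transcripts were measured on 24 arrays from liver, duodenum, jejunum and ileum of wild-type and Casp1-null mice, with 3 arrays per tissue and genotype. Caspase-1 is the protease of inflammasomes, and the series is about its role in the secretion of triglyceride-rich lipoproteins by intestine and liver. Within groups, arrays correlated across probe sets with Pearson's r of 0.9787 to 0.9926. Those r values are across probe sets, which are not independent replicates. The design held no arrays of the Casp1-null background with caspase-1 intact. Genotype differences given below can therefore not be told apart from strain differences, Casp1 itself apart.

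Casp1 transcript (Gene ID 12362) was lower in all 3 intestinal segments of Casp1-null mice. It fell 8.41-fold in jejunum, from 9.30 ± 0.159 in wild type to 6.22 ± 0.364 in Casp1-null (log2, SD, n = 3 each; adjusted p = 3.06e-06). In duodenum it fell 4.21-fold (adjusted p = 0.000166), and in ileum 4.66-fold (adjusted p = 9.28e-05). The 9 wild-type intestinal arrays lay between 8.26 and 9.95 and the 9 Casp1-null arrays between 5.82 and 7.8, so every intestinal array matched its label. In liver, where the signal was low in both genotypes, Casp1 was 4.44 ± 0.198 in wild type and 4.10 ± 0.263 in Casp1-null (SD, n = 3 each) and was not called (adjusted p = 0.503), so the liver labels could not be checked with it. Whether its probe set lies in the deleted part of the gene is not known from the sources used here.

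In fasted liver, Asns, which makes asparagine and is induced by amino acid stress, rose 16.6-fold in Casp1-null mice, from 6.02 ± 0.250 to 10.07 ± 0.152 (log2, SD, n = 3 each; adjusted p = 0.000117). Ces1g, a hepatic carboxylesterase of lipid metabolism, fell 8.08-fold, from 11.05 ± 0.12 to 8.04 ± 0.0587 (n = 3 each; adjusted p = 6.6e-05). Angptl8, a feeding-induced inhibitor of lipoprotein lipase, fell 6.03-fold (SE 0.292 on the log2 scale; adjusted p = 0.018). The steroid enzymes Cyp17a1 and Hsd3b3 moved apart, with log2 changes of 2.56 (adjusted p = 0.0434) and -2.42 (adjusted p = 0.0249). Further large rises were those of Moxd1 (log2 at least 5.31), Cyp2c39 (3.95), Asic5 (3.83), Arhgap6 (2.89), Capn8 (2.60), Igsf23 (2.52), the growth regulator Myc (2.38) and Rnase2a, whose groups were both under the array median. Further large falls were those of Adh6-ps1 (-5.09), the lectin Clec2h (-3.73), Gm3893 (-3.66), the growth factor receptor Erbb4 (-2.65), Cyp2c55 (-2.63), Pttg1 (-2.61) and Cyp2c37 (-2.60), all but the last as lower bounds of the size because the Casp1-null mean was under the array median.

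Genes of lipid handling in the liver changed in small numbers. Of 31 measured genes of lipoprotein assembly and secretion, 3 fell and 28 were not called. The falls were those of Ces1g, Ces1d (-1.11, adjusted p = 0.0123) and Fitm1 (-1.72, adjusted p = 0.0172), which acts in lipid droplet formation, and the list as a whole was not shifted by camera (adjusted p = 0.169), though fry, which tests the list on its own, called it lower (adjusted p = 0.0161). Of 19 genes of fatty acid synthesis only Me1, which supplies NADPH, was called, with a fall of 1.92-fold (adjusted p = 0.0197), and 10 fell when adjusted over the list alone. That list was shifted down by a mean of -0.57 (adjusted p = 2.37e-07), with adjusted p = 0.186 with an estimated correlation. Among 14 lipases, Ces1d and Ces2e (-0.85, adjusted p = 0.0329) fell, 3 fell when adjusted over the list alone, and the list was shifted down (mean -0.22, adjusted p = 0.00946; adjusted p = 0.371 with an estimated correlation), though not without Casp1-null array 1 (0.176). Cd36, a fatty acid transporter, fell 1.86-fold (adjusted p = 0.0236), and its list of fatty acid and sterol uptake was lower by fry (adjusted p = 0.0412) but not by camera (0.168). Gpat3, an acyltransferase of triglyceride synthesis, rose 4.47-fold (adjusted p = 0.0273), and Cyp7b1, of bile acid synthesis, rose 2.34-fold (adjusted p = 0.0111).

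The list of gluconeogenesis and fasting was shifted up in liver by a mean of 0.80 (adjusted p = 9.49e-06; adjusted p = 0.392 with an estimated correlation). Asns was its only member called of 19, and 5 rose when adjusted over the list alone. Relative to the liver mean, the list stood at -0.02, 0.60 and 0.61 in Casp1-null arrays 1, 2 and 3. Wild-type arrays lay between -0.59 and -0.28. Casp1-null array 1 also stood apart from arrays 2 and 3 for fatty acid oxidation and ketogenesis (-0.40 against 0.25 and 0.37). The same held for cholesterol synthesis (0.45 against -0.26 and -0.48). Of 38 genes of xenobiotic metabolism 4 fell, among them Cyp2c55, Cyp2c37 and Cyp2c54 (-1.38), and Sult1e1, the oestrogen sulfotransferase, rose at least 4.18-fold (adjusted p = 0.00288), from a wild-type level under the array median. When adjusted over the list alone, 2 rose and 10 fell, and the list was shifted down (mean -0.31, adjusted p = 0.000749; adjusted p = 0.538 with an estimated correlation). Acute phase genes were shifted up (mean 0.24, adjusted p = 0.00417; adjusted p = 0.688 with an estimated correlation), with 1 of 24 called, Apcs (1.30, adjusted p = 0.0408), and 5 higher and 2 lower over the list alone. Interferon-stimulated genes were shifted down (mean -0.20, adjusted p = 0.000806; adjusted p = 0.392 with an estimated correlation) with 0 of 29 called and 3 lower over the list alone. Lists of B and plasma cells (mean -0.46, adjusted p = 1.8e-06; adjusted p = 0.371 with an estimated correlation) and of T and NK cells (mean -0.15, adjusted p = 0.0302; adjusted p = 0.688 with an estimated correlation) were shifted down, with Fcer2a of 15 B cell genes called, at a level under the array median in both groups, and 0 of 20 T and NK genes. Markers of enterocytes (mean -0.40, adjusted p = 2.77e-07), goblet cells (-0.39, 0.00387), distal intestine (-0.50, 0.000806) and the cell cycle (-0.14, 0.0257) were also shifted down, with 1 member of each list called: Enpep, Zg16, Clec2h and Rrm2. For these lists the adjusted p = 0.371, 0.492, 0.392 and 0.688 with an estimated correlation. On liver arrays the mean over members was 4.558 to 5.228 for B and plasma cells and 4.439 to 4.807 for T and NK cells. For the cell cycle it was 4.813 to 5.099. Such levels lie near or under the lowest liver array median of 5.187, so the sizes of these shifts are not settled. Acute phase genes were no longer shifted without Casp1-null array 2 (0.139), T and NK cells without wild-type array 2 (0.203) or Casp1-null array 1 (0.283), and the cell cycle without wild-type array 3 (0.19) or Casp1-null array 1 (0.164). The other 22 lists were not shifted in liver (adjusted p of 0.0616 to 0.963).

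In total 174 genes were called in liver, 75 higher and 99 lower, of which 51 rose and 54 fell at least 2-fold. At an unadjusted p under 0.05 there were 2416, and 20% of all genes had groups that did not overlap, where chance gives 10%. The count moved to 54 without wild-type array 1, 42 without wild-type array 2, 42 without wild-type array 3, 325 without Casp1-null array 1, 53 without Casp1-null array 2 and 80 without Casp1-null array 3. Of the 38 named genes called in liver, 16 were called in each of those 6 fits, among them Moxd1, Asns, Cyp2c39, Adh6-ps1, Clec2h, Ces1g, Cyp2c55, Cyp2c37 and Sult1e1, whereas the other 22, Angptl8, Cyp17a1, Hsd3b3, Me1, Cd36, Ces1d, Ces2e, Fitm1, Gpat3, Cyp7b1, Apcs and Myc among them, were lost in at least 1.

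**Figure D1:**
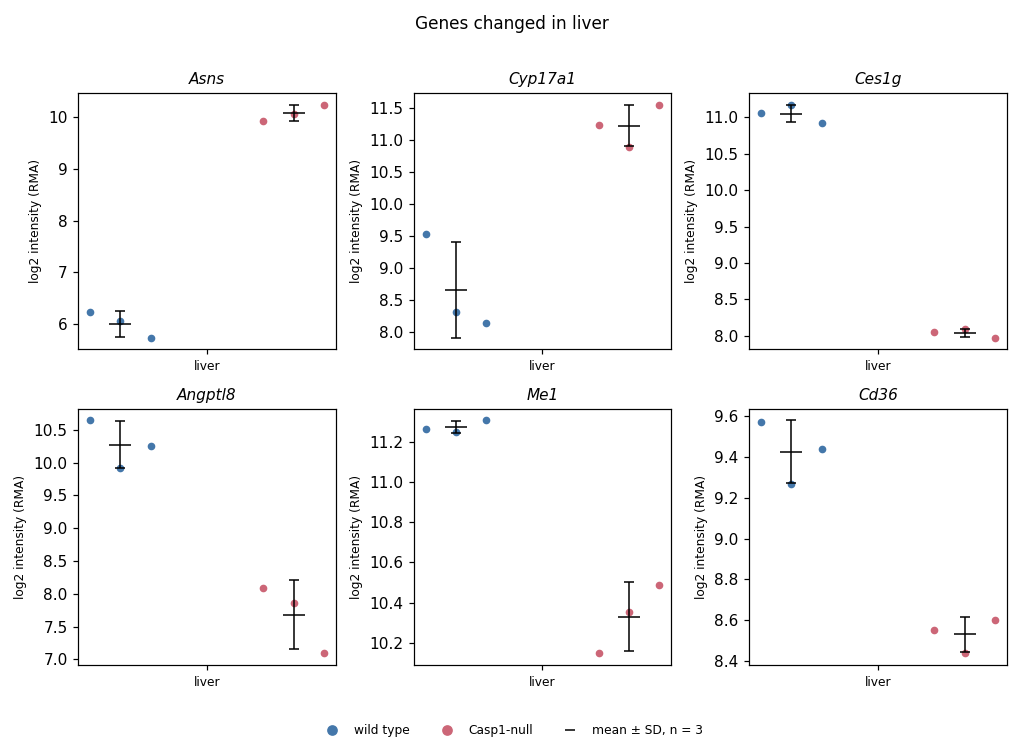
Log2 intensity (RMA) of 6 genes in liver of wild-type and Casp1-null mice, with a point per array and a bar at the mean with its SD (n = 3). Asns and Cyp17a1 were higher in Casp1-null mice and Ces1g, Angptl8, Me1 and Cd36 were lower.

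In the duodenum after an oil load, the drug-metabolising enzyme Cyp2c29 fell at least 44.4-fold, from 9.46 ± 1.46 to 3.99 ± 0.226 (log2, SD, n = 3 each; adjusted p = 1.76e-05). Hsd3b3, a steroid dehydrogenase, fell at least 29.2-fold, from 9.44 ± 0.394 to 4.57 ± 0.101 (n = 3 each; adjusted p = 4.97e-08), and Hsd3b2 fell too (-2.76). Fah, the last enzyme of tyrosine breakdown, rose 7.10-fold (SE 0.350; adjusted p = 0.000508), and Aim2, a sensor of cytosolic DNA, rose 4.80-fold (SE 0.162; adjusted p = 3.29e-06). The immunoglobulin kappa segments Igkv6-20 and Igkv10-96 rose by log2 4.08 and 2.90. Other large rises were Arhgap6 (3.65), Psca (2.42), Pyroxd2 (2.36), Fam183b (2.29) and Prodh2 (2.25), and other large falls were Cbr3 (-2.68), Nlrp9b (-2.36), Ugt2b38 (-2.10), Camk2b (-2.09), Fras1 (-2.03) and Rrm2 (-1.96). The sizes are lower bounds for Cyp2c29, Hsd3b3, Hsd3b2, Cbr3, Fras1, Arhgap6, Psca and Prodh2, whose lower group was under the array median, and Cyp2a12, also among the largest rises, was that low in both groups.

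Of 36 duodenal genes of fatty acid oxidation and ketogenesis, 3 rose and 0 fell, and 6 rose when adjusted over the list alone. They were Eci1 (0.75, adjusted p = 0.0264), Acadl (0.67, adjusted p = 0.0342) and Eci2 (0.57, adjusted p = 0.0488), all enzymes of beta-oxidation. The list was shifted up by a mean of 0.23 (adjusted p = 9.59e-05; adjusted p = 0.352 with an estimated correlation). None of 31 genes of lipoprotein assembly and secretion was called by limma. Cholesterol synthesis was shifted down by a mean of -0.41 with 0 of 21 called (adjusted p = 9.59e-05; adjusted p = 0.789 with an estimated correlation), though not without wild-type array 1 (0.117). Xenobiotic metabolism was shifted down by -0.50 with 2 of 38 fallen, Cyp2c29 and Gsta3 (adjusted p = 2.17e-05; adjusted p = 0.252 with an estimated correlation), and 2 lower over the list alone.

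Among duodenal inflammasome genes Aim2 rose and Nlrc4 (-1.14, adjusted p = 0.00083) and Casp4 (-1.46, adjusted p = 0.015) fell, of 27 measured, and over the list alone 2 rose and 4 fell. Interferon-stimulated genes were shifted down by -0.45 with Oasl2 called of 29 (-1.81, adjusted p = 0.00214), and 1 lower over the list alone (adjusted p = 0.000108; adjusted p = 0.789 with an estimated correlation). MHC class II genes were shifted down by -0.67 with 0 of 8 called and 6 lower over the list alone (adjusted p = 0.000224; adjusted p = 0.708 with an estimated correlation). Genes of endoplasmic reticulum stress were shifted down by -0.22 (adjusted p = 0.000726; adjusted p = 0.789 with an estimated correlation), with 0 of 24 called and 2 lower over the list alone. Shifted up were the cell cycle (mean 0.26, adjusted p = 0.00463; adjusted p = 0.877 with an estimated correlation), B and plasma cells (0.45, adjusted p = 0.0227; adjusted p = 0.877 with an estimated correlation) and myeloid cells (0.42, adjusted p = 0.00687; adjusted p = 0.789 with an estimated correlation). In those lists Rrm2 alone was called, as lower, and over the list alone 3 B cell genes and 1 myeloid gene rose. Exocrine pancreas markers were shifted down by -1.24, with Rnase1 called of 23 (-3.13, adjusted p = 0.0132), and the list had adjusted p = 5.29e-05, or adjusted p = 0.789 with an estimated correlation. These markers lay 2.96 above the duodenal mean in wild-type array 1 and between -0.50 and -0.68 in the other 5 duodenal arrays, and without wild-type array 1 the list was not shifted (adjusted p = 1). Rnase1 itself stood at 10.15 in wild-type array 1, against a mean of 6.10 in the other 5. Its change ran from -3.63 to -2.22 over the alternatives. The cell cycle was no longer shifted without wild-type array 1 (0.0925) or Casp1-null array 3 (0.12), B and plasma cells without wild-type array 3 (0.0949) or Casp1-null array 1 (0.0998), and myeloid cells without Casp1-null array 1 (0.125). The other 24 lists were not shifted (adjusted p of 0.0666 to 0.977). Relative to the duodenal mean, smooth muscle and stroma markers lay between -0.35 and -0.24 in wild type and between 0.12 and 0.38 in Casp1-null arrays. Endothelium markers lay between -0.18 and -0.12 and between 0.04 and 0.24. The pooled spread included ileal wild-type array 2 and Casp1-null array 3, which were high in stroma markers. A difference in cell composition between the duodenal genotypes was thus not excluded.

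In the duodenum 227 genes were called, 113 higher and 114 lower, 50 of them at least 2-fold in each direction, against 2451 at an unadjusted p under 0.05. Groups did not overlap for 22.7% of all genes, where chance gives 10%. Without wild-type array 2 the count was 140, and it was 140 without Casp1-null array 3. Of 29 named genes called, 19 were called whichever array was left out, and Igkv6-20, Igkv10-96, Cyp2a12, Rnase1, Eci1, Acadl, Eci2, Casp4, Lbp and Gsta3 were lost in at least 1 fit.

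In the jejunum of Casp1-null mice Nos2, Duoxa2, Duox2, Ccl20 and Ubd were among the 10 largest falls. Nos2, the inducible nitric oxide synthase, fell 13.3-fold, from 12.12 ± 0.136 to 8.39 ± 0.709 (log2, SD, n = 3 each; adjusted p = 0.00197). Duoxa2 and Duox2, the maturation factor and the catalytic part of an epithelial peroxide-producing oxidase, fell 15.2-fold (SE 0.62; adjusted p = 0.00355) and 11.7-fold (SE 0.699; adjusted p = 0.017). The chemokine Ccl20 fell 12.9-fold (SE 0.496; adjusted p = 0.00104) and the ubiquitin-like Ubd at least 11.2-fold (SE 0.496; adjusted p = 0.00163). Duox2 was no longer called without wild-type array 1 (adjusted p = 0.0875), wild-type array 2 (0.0669), Casp1-null array 1 (0.0773) or Casp1-null array 3 (0.0779), and was called without either of the others (0.0126 and 0.0301). Nos2, Duoxa2 and Duox2 belong to the antimicrobial and Paneth cell list, of which 3 of 17 fell and 4 fell over the list alone, though the list was not shifted (adjusted p = 0.0935).

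Hsd3b3 fell at least 37.8-fold in jejunum, to 3.14 in Casp1-null mice, and the transcription factor Tfcp2l1 fell with a log2 change of -3.13. Other large falls were Gml (-2.80), Adh6a (-2.37), an alcohol dehydrogenase, and Nlrp9b (-2.32). Large rises were Arhgap6 (3.49), Igkv6-20 (3.39), Igkv10-96 (2.83), Fosb (2.61), an immediate early gene, Rdh18-ps (2.56), Prodh2 (2.50), Zfp791 (2.49), Lrat (2.23), which esterifies retinol, Tppp3 (2.10) and Hddc3 (2.09), with the sizes for Arhgap6, Rdh18-ps, Prodh2 and Zfp791 as lower bounds because their wild-type mean was under the array median.

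Of 36 jejunal genes of fatty acid oxidation and ketogenesis 3 rose and 0 fell, and 5 rose over the list alone. Angptl4, an inhibitor of lipoprotein lipase induced by fatty acids, rose 2.59-fold (SE 0.151; adjusted p = 0.000192). Acaa2 rose 2.20-fold (SE 0.132; adjusted p = 0.000302) and Acadl 1.59-fold (SE 0.142; adjusted p = 0.0277), both enzymes of mitochondrial beta-oxidation. The list was shifted up by a mean of 0.24 (adjusted p = 0.00772; adjusted p = 0.923 with an estimated correlation), but not without wild-type array 1 (0.0679). Gpat4 (0.50, adjusted p = 0.0325) and Agpat3 (0.66, adjusted p = 0.0448), acyltransferases of glycerolipid synthesis, rose. Ppargc1a, a coactivator of oxidative metabolism, rose 2.03-fold (adjusted p = 0.00813), and Dbi, an acyl-CoA binding protein, fell 1.49-fold (adjusted p = 0.0397), with a second probe set of Dbi not called (-0.32). Ces1f fell 2.24-fold (adjusted p = 0.00762) and the transporter Abcc3 2.60-fold (adjusted p = 0.00579). None of 31 genes of lipoprotein assembly and secretion was called by limma.

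Of 27 inflammasome genes in jejunum 24 were not called and the list was not shifted (adjusted p = 0.558), while Aim2 rose (1.27, adjusted p = 0.000671) and Nlrc4 (-1.32, adjusted p = 0.000225) and Casp4 (-1.97, adjusted p = 0.00141) fell. In the acute phase list Hamp, which encodes the iron regulator hepcidin, fell at least 2.70-fold (adjusted p = 0.000814) and Lbp rose 3.85-fold (adjusted p = 0.00349). Interferon-stimulated genes were shifted down by -0.51 with Oasl2 called of 29 (-1.78) and 4 lower over the list alone (adjusted p = 3.52e-07; adjusted p = 0.923 with an estimated correlation). Genes of endoplasmic reticulum stress were shifted down by -0.36 with Atf6 called of 24 (-0.43, adjusted p = 0.041) and 8 lower over the list alone (adjusted p = 6.13e-09; adjusted p = 0.858 with an estimated correlation). Xenobiotic metabolism was shifted down by -0.22, with Ahr higher (0.76), Nqo1 (-0.80) and Cyp2a5, under the array median in both groups, lower of 38, and 1 higher and 6 lower over the list alone (adjusted p = 0.0242; adjusted p = 0.923 with an estimated correlation). The cell cycle was shifted down by -0.32 with 0 of 23 called (adjusted p = 0.00772; adjusted p = 0.932 with an estimated correlation). Without wild-type array 2 the last 2 lists were not shifted (0.0771 and 0.293), which left 3 of the 5, nor were they without wild-type array 3 (0.0945 and 0.112), nor xenobiotic metabolism without Casp1-null array 2 (0.108). The other 29 lists were not shifted (adjusted p of 0.0935 to 0.877).

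In the jejunum 387 genes were called, 199 higher and 188 lower, of which 55 rose and 79 fell at least 2-fold, against 2433 at an unadjusted p under 0.05. Groups did not overlap for 19.5% of all genes, where chance gives 10%. The count was 196 without wild-type array 1, 220 without wild-type array 2, 242 without Casp1-null array 3 and 148 with the spread of the 6 jejunal arrays alone. With that spread 28 of 42 named genes were kept, Nos2, Duox2, Duoxa2, Ccl20 and Ubd among them. Of the same 42, 28 were called whichever array was left out, and Igkv6-20, Igkv10-96, Tppp3, Duox2, Gml, Gpat4, Agpat3, Dbi, Acadl, Ahr, Nqo1, Cyp2a5, Atf6 and Birc3 were lost in at least 1 fit.

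**Figure D2:**
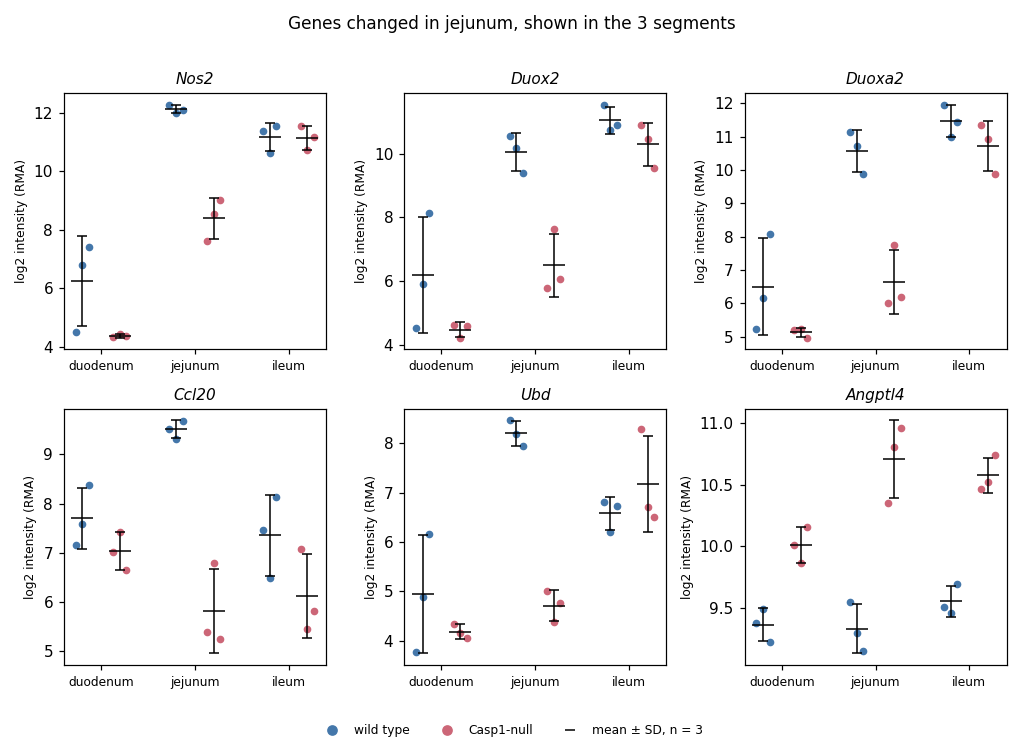
Log2 intensity (RMA) of 6 genes in the 3 intestinal segments of wild-type and Casp1-null mice, with a point per array and a bar at the mean with its SD (n = 3). In jejunum Nos2, Duox2, Duoxa2, Ccl20 and Ubd were lower and Angptl4 was higher in Casp1-null mice.

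In the ileum of Casp1-null mice 2 of 18 genes of fatty acid and sterol uptake, 2 of 36 of fatty acid oxidation and ketogenesis and 1 of 31 of lipoprotein assembly rose. With the spread of the 6 ileal arrays alone none of these 5 was called, and the uptake list was lost with an estimated correlation (adjusted p = 0.215). Fabp1, a cytosolic fatty acid binding protein, rose 3.39-fold (SE 0.212; adjusted p = 0.000381, n = 3 each) and Apoc2, the cofactor of lipoprotein lipase, rose 3.52-fold (SE 0.246; adjusted p = 0.00137). Angptl4 rose 2.03-fold (adjusted p = 0.00316), Acaa2 1.55-fold (adjusted p = 0.0402) and Slc27a2, a fatty acid transporter, 1.72-fold (adjusted p = 0.0241). Hsd3b3 fell at least 41.4-fold, from 8.82 ± 0.297 to 3.45 ± 0.401 (log2, SD, n = 3 each; adjusted p = 1.21e-08), and ccdc198 and the signalling adaptor Pik3ap1 fell at least 29.5-fold and 7.76-fold (adjusted p = 2.19e-07 and 2.89e-07). Reg1, a secreted lectin of regenerating epithelium and pancreas, rose 8.34-fold (adjusted p = 0.009), though not without Casp1-null array 3 (adjusted p = 0.0531).

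Fatty acid oxidation and ketogenesis was shifted up in ileum by a mean of 0.31 (adjusted p = 1.53e-11). Of 36 members Angptl4 and Acaa2 rose, 0 fell, and 6 rose over the list alone. It was the only list in any tissue that stayed shifted with an estimated correlation (adjusted p = 0.03), and it was shifted in all 12 alternatives run for lists. The spread of the 6 ileal arrays alone was not among these 12, so the list was not tested with it. In ileum 3 of 10 splits, the real one included, gave as many shifted lists as the real split. Fatty acid and sterol uptake was shifted up by 0.25 with 2 of 18 risen, Fabp1 and Slc27a2, and 2 over the list alone (adjusted p = 0.0105; adjusted p = 0.215 with an estimated correlation). Lipoprotein assembly and secretion was shifted up by 0.16 with Apoc2 risen of 31 and 2 over the list alone (adjusted p = 0.00378; adjusted p = 0.426 with an estimated correlation). Fatty acid synthesis was shifted up by 0.10 with 0 of 19 called (adjusted p = 0.0444; adjusted p = 0.468 with an estimated correlation). Enterocyte markers were shifted up by 0.15 with Fabp1 called of 23 and 2 risen over the list alone (adjusted p = 0.00899; adjusted p = 0.712 with an estimated correlation).

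Genes typical of proximal intestine were shifted up in the Casp1-null ileum by a mean of 0.50 (adjusted p = 0.000143; adjusted p = 0.426 with an estimated correlation). Fabp1 alone of 17 was called over all genes, while over the list alone 8 rose, including Cybrd1 (2.29), Lct (1.21) and Pdx1 (0.76), and Slc40a1 fell (-0.98). Other large rises were Arhgap6 (3.86), Zfp791 (2.90), Sult6b2 (2.76), Psg28 (2.67), Fah (2.53), Amph (2.53), the alkaline phosphatase Akp3 (2.46), Tmprss15 (2.19), which activates trypsinogen, and Pyroxd2 (1.94). Other large falls were Slc25a48 (-2.60), the tight junction gene Cldn8 (-2.26), Cstdc4 (-2.25), Tfcp2l1 (-2.13), Frmd3 (-2.04), Hsd3b2 (-1.95) and Cyp2c68 (-1.81). The sizes for Arhgap6, Zfp791, Psg28, Amph, Tmprss15, Frmd3 and Hsd3b2 are lower bounds, since their lower group was under the array median. Aim2 rose (0.90) and Nlrc4 (-0.78) and Casp4 (-1.40) fell, of 27 inflammasome genes. Immediate early and heat shock genes (mean 0.26, adjusted p = 0.000358; adjusted p = 0.426 with an estimated correlation) and T and NK cell genes (0.215, adjusted p = 0.00837; adjusted p = 0.712 with an estimated correlation) were shifted up with 0 called. Shifted down with 0 called were the cell cycle (-0.31, adjusted p = 0.000358; adjusted p = 0.639 with an estimated correlation), endoplasmic reticulum stress (-0.14, adjusted p = 0.00899; adjusted p = 0.637 with an estimated correlation) and enteroendocrine and tuft cells (-0.18, adjusted p = 0.00899; adjusted p = 0.426 with an estimated correlation). The neighbours of Casp1 were shifted down by -0.14 with Casp4 called of 30 (adjusted p = 0.015; adjusted p = 0.426 with an estimated correlation). The other 22 lists were not shifted (adjusted p of 0.076 to 0.889).

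Smooth muscle and stroma markers lay 2.23 above the ileal mean in wild-type array 2 and 2.03 above it in Casp1-null array 3, and between -0.93 and -1.16 in the other 4 ileal arrays. Without both arrays, an alternative chosen after seeing the data, 3 lists were shifted, fatty acid oxidation and ketogenesis and enteroendocrine and tuft cells among them, and the lists of lipid uptake, lipoproteins, enterocytes and proximal intestine were not. Without wild-type array 2 alone the cell cycle (adjusted p = 0.804), enterocyte (0.499) and T and NK cell (0.836) lists turned their direction, and those of lipoproteins (0.259), lipid uptake (0.0508), proximal intestine (0.0807) and neighbours of Casp1 (0.353) were no longer shifted. Without Casp1-null array 3 the calls of lipid uptake (0.44), fatty acid synthesis (0.44), endoplasmic reticulum stress (0.253), enterocytes (0.0748) and enteroendocrine and tuft cells (0.11) ended. Without Casp1-null array 2 those of immediate early genes (0.11), T and NK cells (0.103), neighbours of Casp1 (0.244) and fatty acid synthesis (0.243) ended, and without wild-type array 1 or 3 those of fatty acid synthesis (0.279 and 0.152), endoplasmic reticulum stress (0.0991 and 0.0761) and enteroendocrine and tuft cells (0.118 and 0.079). In the ileum 168 genes were called, 79 higher and 89 lower, of which 40 rose and 44 fell at least 2-fold, against 1299 at an unadjusted p under 0.05, and groups did not overlap for 9.23% of all genes where chance gives 10%. The count was 117 without both arrays, 109 without Casp1-null array 3 and 23 with the spread of the 6 ileal arrays alone. On data simulated with each tissue's own spread, 41% of ileal calls made with the pooled spread were false. Of 29 named genes called, 11 were kept and 18 lost with the spread of the 6 ileal arrays alone, the kept ones including Casp1, Hsd3b3, ccdc198, Pik3ap1, Cldn8, Tfcp2l1 and Arhgap6, and 19 were kept and 10 lost without both stroma-rich arrays. Whichever array was left out, 20 were called, and Reg1, Sult6b2, Akp3, Tmprss15, Slc27a2, Acaa2, Aim2, Nlrc4 and Casp4 were lost in at least 1 fit.

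**Figure D3:**
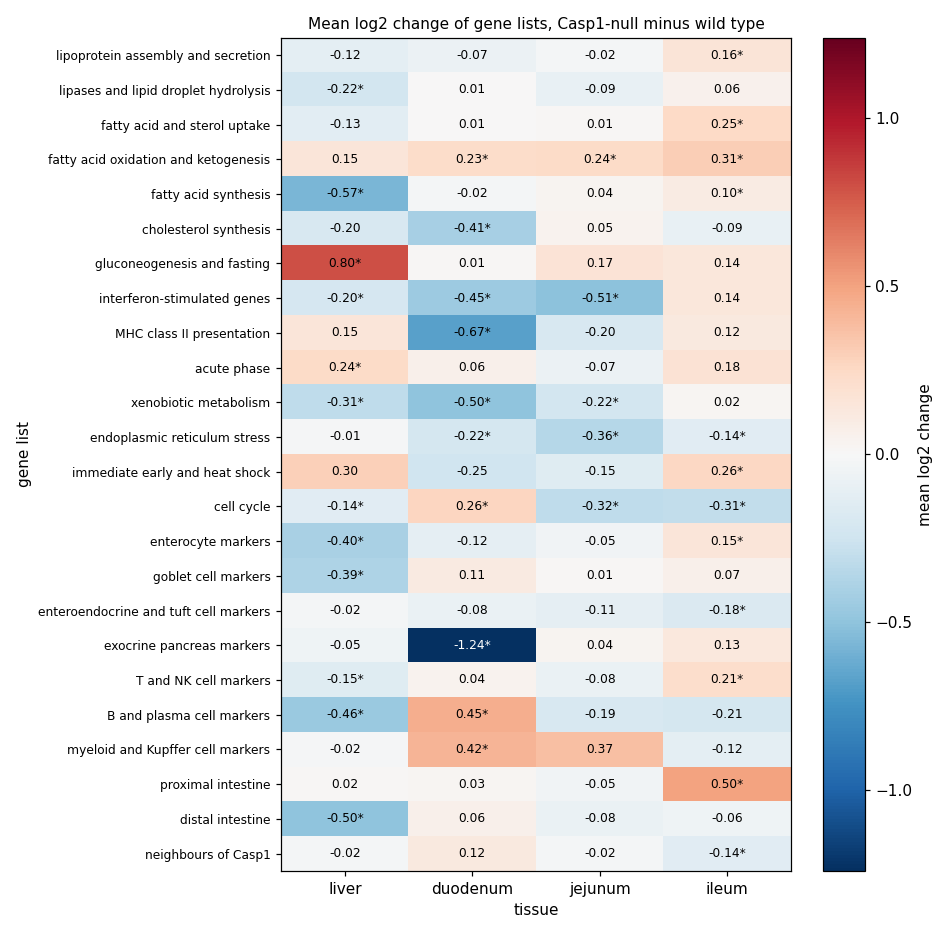
Mean log2 change (Casp1-null minus wild type) of 24 gene lists in the 4 tissues, with colour and printed value giving the mean over measured members and an asterisk marking camera adjusted p under 0.05. Fatty acid oxidation and ketogenesis was shifted up in duodenum, jejunum and ileum, and interferon-stimulated genes were shifted down in liver, duodenum and jejunum, but of these 6 calls only ileal oxidation held with an estimated correlation (adjusted p = 0.03; 0.352 and 0.923 for oxidation in duodenum and jejunum, and 0.392, 0.789 and 0.923 for interferon).

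**Figure D4:**
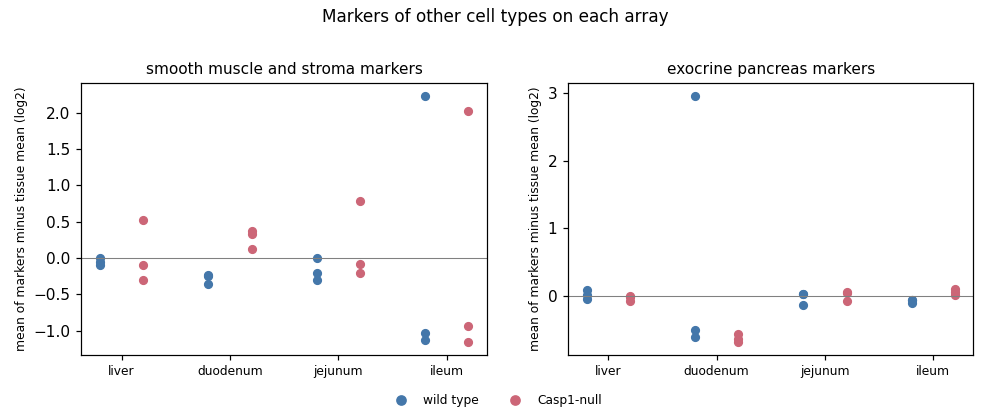
Mean of the smooth muscle and stroma markers and of the exocrine pancreas markers on each of the 24 arrays, as log2 difference from the mean of the tissue, with a point per array. Ileal wild-type array 2 (2.23) and Casp1-null array 3 (2.03) stood apart for stroma markers, and duodenal wild-type array 1 (2.96) for pancreas markers.

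On average over the 3 segments, Hsd3b3 fell with a log2 change of -5.16 (SE 0.091; adjusted p = 6.28e-06), a lower bound of its size, Casp1 with -2.46 (adjusted p = 0.000525) and Tfcp2l1 with -2.15 (adjusted p = 0.000214). Nnt, the mitochondrial proton-translocating transhydrogenase, rose with 1.40 (adjusted p = 0.000525). The other genes with the smallest p were Camk2b (-1.82), the ribosomal protein gene Rpl34 (-1.44), Hddc3 (1.95), Ppfibp1 (1.21), B3gnt3 (-1.41) and Churc1 (-1.17), and all 10 were called whichever genotype and replicate number was left out. In total 390 genes were called, 186 higher and 204 lower, of which 298 were also called in a segment and 92 were not. The labels do not say that a number is the same mouse in every segment. The count was 186, 223 and 161 without wild-type number 1, 2 or 3, and 202 and 240 without Casp1-null number 1 or 2.

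Genotype differences depended on the segment for 22 genes by the interaction test, against 1047 at an unadjusted p under 0.05, and all 22 were called in at least 1 segment. Pik3ap1 changed by -2.96 in ileum, against 0.01 in duodenum and -0.37 in jejunum (interaction adjusted p = 0.00013), and ccdc198 by -4.88 in ileum (0.00013). Cldn8 (-2.26 in ileum; 0.00107) and Hao2, a peroxisomal oxidase (-1.71 in ileum; 0.00233), also differed most in ileum. Cbr3 (-2.68; 0.00113), Pzp (-1.24; 0.0013) and Cyp2c29 (-5.47; 0.00615) had their largest change in duodenum, and Tnip3, an inhibitor of NF-kappaB signalling (-1.93; 0.00113), and Pglyrp1, a peptidoglycan recognition protein (-1.65; 0.00814), in jejunum. Ciapin1 changed by -0.36 in duodenum, 0.60 in jejunum and 0.79 in ileum (0.00113). Fabp1, with 0.05, -0.11 and 1.76, was among the 22 as well (0.0354). For ccdc198, Tnip3, Cbr3, Pzp, Hao2 and Cyp2c29 the Casp1-null mean in the segment of the largest change was under the array median, which makes that size a lower bound. For these and Cldn8 both groups were that low in the other segments, where a genotype difference could not be measured. The count was 13, 9 and 10 without wild-type number 1, 2 or 3, and 10 without Casp1-null number 1. With the replicate number as a block limma called 0 genes, against 829 at an unadjusted p under 0.05.

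The genotype difference in liver differed from that in intestine for 523 genes, against 2707 at an unadjusted p under 0.05, and 222 of the 523 were called in a tissue. Asns rose by log2 4.07 more in liver than on average in the segments (adjusted p = 5.09e-08), and the same held for Capn8 (2.96; 3.13e-09) and Igsf23 (2.85; 1.05e-08). Clec2h (-3.73; 1.25e-08) and Serpinb1a, a protease inhibitor (-2.06; 3.13e-09), were lower in liver relative to intestine, with lower bounds as sizes because the Casp1-null liver mean was under the array median. The test also called Adh6-ps1 (9.61e-15), Cyp2c39 (8.4e-12), Gm3893 (2.64e-10), Asic5 (9.33e-11) and Moxd1 (2.31e-08), which were under the array median in both groups of every segment. That was so for 147 of the 523 genes, and 83 were that low in both liver groups (39 in liver and in every segment), so for these no difference between the organs was measured. Liver and intestine also differed in fasting and feeding state, since intestine was taken after oil.

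Genes changed the same way in several tissues more often than chance gives for independent lists. There were 169 genes called in the same direction in at least 2 tissues, 74 in at least 3 (32 higher, 42 lower) and 21 in all 4 (7 higher, 14 lower), and 2 genes of 690 called were opposite in 2 tissues. Duodenum and jejunum shared 62 higher and 68 lower genes, where 1.2 and 1.1 were expected of independent lists. Liver and ileum shared 8 and 20, where 0.31 and 0.47 were expected. The labels say that each small intestine was divided into the 3 segments, and the segments were tested with a pooled spread. Lists of different segments are therefore not independent, and the expected counts do not hold for them. By the rule for named genes, the 20 of the 74 genes with the largest fitted mean change over the 4 tissues were Hsd3b3 (-4.48), Arhgap6 (3.48), Zfp791 (2.02), Casp1 (-1.93), Hddc3 (1.80), Fah (1.80), Camk2b (-1.77), Tfcp2l1 (-1.71), Ocel1 (1.56), Rpl34 (-1.50), Pyroxd2 (1.49), Mboat2 (1.47), Hsd3b2 (-1.45), the complement regulator Cfi (-1.43), Cyp2c68 (-1.39), Nnt (1.35), Pttg1 (-1.30), Myo7a (-1.30), Casp4 (-1.25) and B3gnt3 (-1.24). Their order is not settled, nor are the sizes for Hsd3b3, Arhgap6, Zfp791, Casp1, Camk2b, Mboat2, Hsd3b2, Cfi and Pttg1, each of which had at least 1 group under the array median in some tissue. Nnt rose in each tissue, by 1.22 in liver, 1.43 in duodenum, 1.51 in jejunum and 1.24 in ileum.

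**Figure D5:**
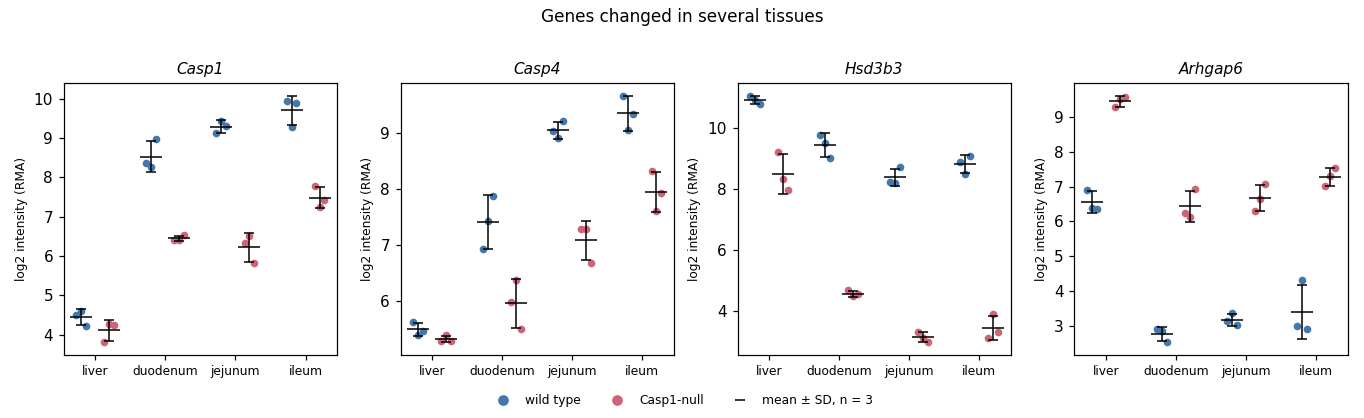
Log2 intensity (RMA) of Casp1, Casp4, Hsd3b3 and Arhgap6 in the 4 tissues of wild-type and Casp1-null mice, with a point per array and a bar at the mean with its SD (n = 3). Hsd3b3 was lower and Arhgap6 higher in Casp1-null mice in all 4 tissues, and Casp1 and Casp4 were lower in the 3 intestinal segments.

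Of 30 measured neighbours of Casp1, its close homologue Casp4 was called in duodenum, jejunum and ileum, with Birc3 (-0.64) in jejunum and Pdgfd (-1.06, a lower bound of the size) in liver. That was 3.33% of neighbours against 0.921% of other genes in liver and 6.67% against 2.04% in jejunum. Fisher's exact test, two-sided, gave p = 0.243 in liver, 0.304 in duodenum, 0.126 in jejunum and 0.235 in ileum, so more frequent calls among neighbours were not shown.

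Wild-type segments differed along the known axis of the intestine. Duodenum exceeded jejunum for Tmprss15 (log2 7.61), the iron exporter Slc40a1 (7.01), Slc16a9 (6.71), the calcium-binding S100g (6.86), Pdx1 (5.99), Cybrd1 (4.59) and Slc46a1 (3.77), and was lower for Slc34a2 (-7.42), Slc5a8 (-6.60), Nos2 (-5.88), Enpp7 (-5.33) and Slc10a2 (-4.80). Ileum exceeded jejunum for the bile acid genes Fabp6 (6.99), Slc10a2 (3.05) and Fgf15 (2.68) and for Slc6a14 (5.42), Slc25a48 (4.49) and ccdc198 (4.38), and was lower for the lactase gene Lct (-6.38), Slc23a1 (-6.06), Cyp2b10 (-5.45), Gip (-4.29) and Gata4 (-4.19). The sizes for Tmprss15, Slc40a1, Slc16a9, Pdx1, Cybrd1, Slc34a2 and Slc10a2 in duodenum and for Fgf15, Slc6a14, Slc25a48, ccdc198 and Slc23a1 in ileum are lower bounds, since the lower group was under the array median. Of 17 proximal genes 6 were higher and 1 lower in duodenum, and 1 higher and 11 lower in ileum, and of 15 distal genes 0 were higher and 7 lower in duodenum, and 8 higher and 1 lower in ileum. In total 1460 genes were called between duodenum and jejunum (825 higher and 635 lower in duodenum) and 2906 between ileum and jejunum (1638 higher and 1268 lower in ileum). The first count was 880 and 906 without duodenal wild-type array 1 or 2 and 894 without jejunal wild-type array 3, and the latter was 1869 without jejunal wild-type array 1 and 1608 with the spread of the 6 arrays compared. The same contrasts in Casp1-null mice called 1101 genes, 730 of them shared and 0 opposite, and 2418 genes, 1721 shared and 1 opposite.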

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

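The 20 genes named next were called by interaction tests fixed beforehand, and the 3 tests of the jejunal pattern were chosen after its values had been seen.

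These genes stood out because their genotype difference differed between duodenum, jejunum and ileum by the interaction test in limma. Changes had the largest size in ileum for Pik3ap1 (adjusted p = 0.00013), ccdc198 (0.00013), Cldn8 (0.00107), Ciapin1 (0.00113) and Hao2 (0.00233). They had the largest size in duodenum for Cbr3 (0.00113), Pzp (0.0013) and Cyp2c29 (0.00615), and in jejunum for Tnip3 (0.00113) and Pglyrp1 (0.00814). For ccdc198, Cldn8, Hao2, Cbr3, Pzp, Cyp2c29 and Tnip3 both groups were under the array median in the other 2 segments, where no difference could be measured.

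A further 10 genes stood out because the interaction test called their genotype difference in liver as unlike that in the mean of the segments. Relative to intestine the liver difference was lower for Adh6-ps1 (adjusted p = 9.61e-15), Gm3893 (2.64e-10), Serpinb1a (3.13e-09) and Clec2h (1.25e-08). It was higher for Cyp2c39 (8.4e-12), Asic5 (9.33e-11), Capn8 (3.13e-09), Igsf23 (1.05e-08), Moxd1 (2.31e-08) and Asns (5.09e-08). Adh6-ps1, Gm3893, Cyp2c39, Asic5 and Moxd1 were under the array median in both groups of every segment. For these no difference between the organs was measured. Liver and intestine also differed in feeding state.

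The fall of Nos2, Duox2, Duoxa2, Ccl20 and Ubd in Casp1-null jejunum was set against 3 explanations. Immune cell markers did not fall to the same extent. The lowest median over the 3 immune lists was -0.232, for B and plasma cells (SD 0.837 over 15 genes). It was also -0.232 as the lowest with only members over the array median, against -3.49 for the smallest fall of the 5 genes. A median over a list cannot show the loss of a small group of cells, so fewer immune cells were not excluded. A single jejunal array did not carry the fall of the 5 genes, since at least 89.6% of each change remained without any 1 of the 6 arrays. Duox2, however, then missed the threshold in 4 of the 6 fits (adjusted p from 0.0126 to 0.0875). A weaker epithelial response to bacteria in the Casp1-null mice is a candidate that was not shown. Other genes of a list of bacterial response genes were lower (camera p = 2.69e-05, or 0.0248 with an estimated correlation). Of 19 measured genes 17 were negative, with a median of -0.393 and 2 called, Cxcl16 (-1.09) and Nfkbia (-0.74). That list was written after the falls had been seen and was tested on the same arrays. The antimicrobial and Paneth cell list, fixed beforehand, was not shifted by camera (adjusted p = 0.0935). A difference in the bacteria the mice carried, which the labels do not describe, stays open as untested, and the segments were not shown to differ for these 5 genes (interaction adjusted p of 0.108 to 0.903).

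Other splits of the samples were counted for each result. With 3 arrays against 3 there are 10 splits, too few for a share under 0.05. The real split called 174 genes in liver (highest other 0), 227 in duodenum (0), 387 in jejunum (2), 168 in ileum (14), 390 on average over segments (0), 1460 between wild-type duodenum and jejunum (0) and 2906 between wild-type ileum and jejunum (0), and for each of these 1 split, the real one, gave as many. For the shifted lists 1 split gave as many as the real 12 in liver (highest other 11), 3 as many as 10 in duodenum (11), 4 as many as 5 in jejunum (9) and 3 as many as 12 in ileum (12). For the difference between segments, 2 of 100 splits, the real one included, gave as many as the real 22 genes. The highest other split gave 612. Exchanging genotype labels within a segment turns genes shared by all segments into differences between segments. Such splits do not stand for arrays without an interaction, so they could not exclude chance. For liver against intestine 1 of 100 splits, the real one, gave as many as the real 523 (highest other 326). These splits were drawn in the same way and could not exclude chance either.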

How the results depend on the processing

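The alternatives with named genes only and without both stroma-rich ileal arrays, and the gene-order windows around Casp1, were chosen after seeing the data. Of the counts under all alternatives 107 stayed within 1.5 times of the value reported and 54 moved further, and of single genes and lists 2274 values kept direction and side of the threshold, 479 no longer passed it and 5 reversed, all 5 in ileal lists. The lists reversed without wild-type array 2, where their adjusted p was highest among the fits that each left out 1 array: the cell cycle (5.2e-09 to 0.804), enterocyte markers (3.38e-07 to 0.499) and T and NK cells (1.94e-05 to 0.836). Without both stroma-rich arrays the cell cycle (0.517) and enterocyte markers (0.321) reversed. The cause was not tested.

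With an estimated correlation 0 lists were shifted in liver, 0 in duodenum, 0 in jejunum and 1 in ileum, and with fry 6, 1, 0 and 1. In liver 4 of the 6 were also called by camera and 2 were not, lipoprotein assembly and secretion (fry adjusted p = 0.0161) and fatty acid and sterol uptake (0.0412). Above the median 7 lists were shifted in liver. Those of B and plasma cells, T and NK cells, goblet cells and distal intestine had too few members there to be tested. Without both stroma-rich arrays 3 lists were shifted in ileum. With the replicate number as a block, which takes up degrees of freedom, the counts of genes were 47 in liver, 117 in duodenum, 180 in jejunum, 93 in ileum, 135 on average over segments, 0 for the segment interaction, 270 for liver against intestine and 92 shared by at least 2 tissues. With that block 34 genes were shared by at least 3 tissues and 5 by all 4. Pairing of samples by number was not shown. Residuals of samples with 1 number correlated at -0.376 to 0.304 between genotypes (over 0.1 in 1 of 12 pairs). Between segments they correlated at -0.0978 to 0.173 (over 0.1 in 5 of 18 pairs), which leaves open whether a number is a mouse. The spread of other arrays gave 626 genes in liver (all 24 arrays), 148 in jejunum and 23 in ileum (their own 6 arrays), and 1608 for wild-type ileum. Named genes only gave 488 in liver, array weights 363 in duodenum and an unadjusted p under 0.01 gave 532 genes shared by at least 2 tissues. In the 18-array fit the mean over segments gave 796 genes with genotype and number as random blocks and 977 with independent arrays, and above the median 12 genes showed a segment interaction. Except where the construction is named, the cause was not tested.

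Leaving out each array in turn gave 42 to 325 genes and 11 to 14 lists in liver, 140 to 190 and 7 to 11 in duodenum, 196 to 308 and 3 to 6 in jejunum, and 109 to 168 and 8 to 15 in ileum. It gave 161 to 265 genes on average over segments, 9 to 15 for the segment interaction, 880 to 1167 for wild-type duodenum and 1869 to 2974 for wild-type ileum. The arm with 2 arrays is then smaller, which lowers power. No scaling moved the median change of all genes by over 0.1. Windows of 5 Mb and 20 Mb around Casp1 were not run because no build is named, and windows of 50 and 200 genes changed no call (Fisher's exact p of 0.1 to 1). Signal near background limited liver Casp1.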

Other observations

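The tests of probe binding, of loss of caspase-1 and of the ileal arrays were chosen after the results had been seen, and so were the genes in the next 2 paragraphs, whereas the clustering test was not.

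Among genes of the inflammasome, some were called and others were not. Beside Aim2, Nlrc4 and Casp4, the intestinal sensor Nlrp9b fell 5.14-fold in duodenum and 4.99-fold in jejunum (adjusted p = 0.00726 and 0.00696), with a change of -1.59 in ileum that was not called (0.124). Nlrp6, a further sensor, stood at 10.27, 9.75 and 9.90 (log2) in wild-type duodenum, jejunum and ileum and differed by -0.06, 0.27 and 0.11, which was not called (adjusted p = 0.907, 0.524 and 0.999). The adaptor Pycard had differences of 0.19, -0.11 and -0.02, and the pore-forming substrate Gsdmd -0.25, -0.42 and 0.32, again without a call. Il18, a cytokine that caspase-1 matures, was expressed at 10.01, 9.45 and 7.96 in wild type and differed by 0.00, -0.39 and 0.03. Il1b had a low signal of 4.61, 4.61 and 4.67 in wild type and was not called in any segment. Aim2, Nlrc4 and Casp4 are among the 74 genes called in the same direction in at least 3 tissues. For these a strain difference was not excluded.

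Duox2 and Duoxa2 had their highest wild-type means in ileum, and Nos2 in jejunum. Nos2 stood at 6.25 ± 1.53 in duodenum, 12.12 ± 0.136 in jejunum and 11.18 ± 0.478 in ileum (log2, SD, n = 3 each), Duox2 at 6.19, 10.04 and 11.05, and Duoxa2 at 6.50, 10.57 and 11.46. In Casp1-null mice Nos2 was at 4.38, 8.39 and 11.14 in the same order, Duox2 at 4.48, 6.49 and 10.29, and Duoxa2 at 5.13, 6.64 and 10.71. Ubd had its highest wild-type mean, 8.20, in jejunum, against 4.94 in duodenum and 6.58 in ileum.

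The 74 genes called in the same direction in at least 3 tissues were weighed against strain differences and loss of caspase-1. A strain variant that lowers probe binding cannot explain the 32 higher genes if wild-type mice carry the reference sequence, and for the 42 lower genes it cannot be told apart from lower expression, because no probe sequences were used. Stretches of chromosome from another strain may explain part of the set, since 28 of the 74 had another member within 10 genes, against a median of 6 and a maximum of 21 in random sets (permutation p = 1e-04, the smallest that 10000 sets can give), in 14 pairs of which 8 moved in opposite directions, and 8 of the 28 were among the 21 genes called in all 4 tissues, a set too small to test alone (2 near another of the 21, permutation p = 0.211). Casp4, next to Casp1 and known as a passenger mutation in Casp1-null mice, and Nnt, known to be deleted in C57BL/6J, are both in the set. Aim2 is 1 of the 28, paired with Dusp23, and Nlrc4, also in the set, lay near another called gene in duodenum and jejunum. All called genes of a tissue, shared ones included, clustered in each tissue. Near another lay 121 of 227 in duodenum (random median 50), 184 of 387 in jejunum (136) and 85 of 168 in ileum (28). The permutation p was 1e-04 in each segment. In liver 49 of 174 lay near another (random median 29, permutation p = 0.0019). Genes called in 1 tissue only clustered in duodenum (permutation p = 0.0095) but not in liver (0.699), jejunum (0.405) or ileum (0.117). Loss of caspase-1 itself cannot be told apart from a strain difference for these 74 genes, Casp1 itself apart, because the design holds no arrays of the Casp1-null background with caspase-1 intact. The same limit holds for every other genotype difference given here.

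High smooth muscle and stroma markers in ileal wild-type array 2 and Casp1-null array 3 were set against 3 explanations. An array of another segment was excluded, as 0 of the 2 arrays had Fabp6 nearer to jejunum (12.35 and 12.47, against 12.41 in the other ileal arrays and 5.51 in wild-type jejunum), and so was an exchange of genotypes, as 0 had Casp1 in the range of the other genotype (9.28 and 7.42). Muscle or stroma in the scraped sample is a candidate explanation that was not tested. The median marker exceeded the other 4 ileal arrays by 2.2 in the first and 3.13 in the other, with 15 and 14 of 19 markers over log2 1 higher. The 2 arrays were picked because these same markers were high, so this excess was fixed in advance. Myh11 stood at 10.7 and 9.90 against 4.33 and Acta2 at 12.31 and 11.51 against 5.24, while scraping is meant to leave muscle behind. The excess was smaller for the collagen gene Col1a1, at 5.70 and 5.65 against 5.16. No biological explanation was tested, since each genotype held 1 such array.

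Duodenal wild-type array 1 carried a further marker signal, with 17 of 23 exocrine pancreas markers over log2 1 higher than in the other 5 duodenal arrays and a median difference of 4.06. Cpa1 stood at 12.04 there against 4.60, Ctrb1 at 12.36 against 4.94 and Cel at 9.82 against 3.24.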
